A study of Mus musculus with 2 samples.

How the data were processed

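Mature miRNAs were measured in total RNA of mouse embryonic stem cells that were left to differentiate as embryoid bodies, cell aggregates that form in suspension. The cells were ATCC line CRL-1934, known as ES-D3, of strain 129S2/SvPas, grown with 15% fetal bovine serum. RNA of day 0 and of day 10 was labelled with Cy5, and each day had 1 array, per the labels. The probes covered release 19 of the miRBase catalogue.

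Spot intensity was used as deposited in the scanner files, where it is a linear median density per spot, per the file headers. No header or label stated a background subtraction or a normalization for it, and the files had no background column. Each array held 3968 spots. Of these, 3795 spots belonged to 1265 mature miRNA probes with 3 spots each, 148 to 19 spike-in probes, 20 to 5 probes for 5S rRNA, and 5 were blank. Spot signals ran from 33.6 to 55402 on the day 0 array and from 31.6 to 52557 on the day 10 array. A further table held the authors' processed intensity per probe on a linear scale, with column medians of 25.4 for day 0 and 22.0 for day 10. Its ranks followed the scanner signal of the same array (Spearman rho 0.998 and 0.996 across probes), while its background subtraction and its scaling between arrays are not given in the sources used here. It entered as an alternative, as log2 of the value plus 50.

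Signals were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50 and all spots in the fit. They were then log2 transformed, control spots were left out, and the arrays were quantile normalized to each other. The level of a probe is the mean over its 3 spots. The offset shrinks differences of dim probes, so folds are on the scale of corrected signal plus 50 and understate the change of dim miRNAs. A probe counted as detected where the median of its spots lay above the 95th percentile of the 5 blank spots of that array, which was 70.0 on day 0 and 71.4 on day 10. With 5 blank spots this threshold is itself imprecise.

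With 1 array per day there is no replicate check, so no test was run and no p-value is given. The number of arrays limits the precision, and the SD over 3 spots of a probe is technical: it holds none of the variation between cultures. A miRNA was counted as higher or lower on day 10 where the log2 difference was at least 1 in size and the brighter array detected the probe. Where the dim array did not detect it, the fold is given as at least the normalized level of the brighter array over the higher of the probe's own level and the lowest detected level on the dim array. Correlations are across probes detected on at least 1 array, and probes are not independent replicates.

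A total of 17 lists of miRNAs were fixed before the data were examined, together with the rules of detection and size, the main settings and most alternatives. They were the miR-290 (miR-290 to miR-295), miR-302-367, miR-17-92 with paralogous, miR-183-96-182, Sfmbt2 intron, Dlk1-Dio3 and X-linked testis clusters, the let-7 and miR-98 family, miRNAs of the Hox clusters, targets of p53, and miRNAs typical of muscle and heart, neural tissue, blood, endothelium, mesenchyme and fibroblasts, epithelium, and endoderm and liver. Both arms of a precursor counted. Each list's median difference over detected probes was set against 10000 random lists of the same size, matched on mean level in 10 bins, which describes these 2 arrays and is not a test. Named miRNAs were the 8 with the largest difference in each direction among probes at or above the median detected level of the brighter array, the 3 brightest of each array, and from each list the 2 with the largest difference under the same condition on level, or else the 2 brightest. Any other name was chosen after its values were seen. A set of 13 probes matched several mature miRNAs, and such a probe is named with its partners.

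After the results had been seen to shift with the scaling between arrays, each list median was also expressed relative to the median of all detected probes. Such a relative median cannot change under a scaling that shifts all differences alike. The planned measure remains the list median itself, and both are given. Alternatives were another offset, no background correction, 75th percentile scaling, cyclic loess, no normalization, spike-in probes set equal, the authors' values, medians over spots, subsets of spots, other detection filters and a 4-fold threshold. Subtracting the blank spots, setting the 5S rRNA probes equal and doubling the detection threshold were added after the data were seen.

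The procedure was tested on simulated arrays with the measured levels and spot spread, a weaker day 10 array, and changes placed in probes of above-median level. Among 1265 probes, it recovered 38 of 40 probes made 4-fold higher, 37 of 40 made 4-fold lower, 19 of 20 made 8-fold higher and 20 of 20 made 8-fold lower. At exactly 2-fold it recovered 2 of 40 higher and 15 of 40 lower, and it called 3 of 1065 unchanged probes. The simulated arrays differed only by a common scale, spot noise and the placed changes, as many higher as lower. They held no variation between cultures or between arrays in single probes, so these rates do not give the rate of false calls here.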

Results

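The miRNA content of embryoid bodies was profiled on 1 single-colour array for day 0 and 1 for day 10 of differentiation, which addressed how miRNA expression differs between these days. The day 0 array detected 738 of the 1265 mature miRNA probes (58.3%) and the day 10 array 476 (37.6%). Both arrays detected 475 probes, day 0 alone 263 and day 10 alone 1. Before normalization, the 739 probes detected on at least 1 array had a median signal of 189 on day 0 and 97.9 on day 10. Their median log2 difference, day 10 minus day 0, was -0.78, and 675 of them were below 0. The 19 spike-in probes had a median difference of -0.24 (SD 0.17 over probes) and the 5 probes for 5S rRNA a median of 0.21 (SD 0.20). After quantile normalization the median difference of the 739 probes was 0.024, so the differences below are relative to the bulk of detected miRNAs. There was no replicate array, and the SDs below are over the 3 spots of a probe.

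The 2 profiles had a Pearson r of 0.915 and a Spearman rho of 0.848 across the 739 probes. In total, 50 miRNAs were at least 2-fold higher on the day 10 array and 77 at least 2-fold lower, with 4 and 7 of them at 4-fold. Of the 77, 16 were not detected on the day 10 array. For some of these the fold can only be given as at least a value under 2, such as 1.54 for miR-5620-3p. Of the 50, 39 belonged to the fixed lists, and of the 77, 29 did. The balance of directions may in part come from the procedure. On simulated arrays it recovered 15 of 40 probes made 2-fold lower but 2 of 40 made 2-fold higher. At 4-fold it recovered 37 of 40 lower and 38 of 40 higher. The balance also depended on the scaling between arrays. It was 106 higher and 55 lower with 75th percentile scaling, 34 and 86 with cyclic loess, 38 and 96 in the authors' values, and 6 and 187 with the spike-in probes set equal. Without normalization it was 6 and 232, and with the 5S rRNA probes set equal 3 and 304. In scanner signal with neither background correction nor normalization, 40 of the 50 were brighter on day 10, and all 77 were dimmer. In the setting without normalization, which keeps the background correction, 7 of the 50 were below 0.

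**Figure D1:**
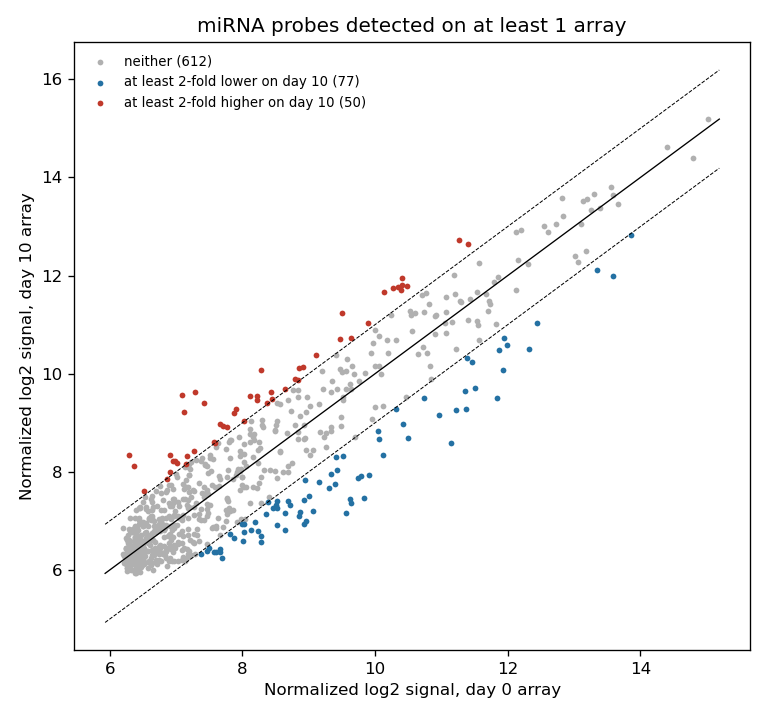
Normalized log2 signal of each of the 739 detected miRNA probes on the day 0 array (x axis) and the day 10 array (y axis), 1 point per probe. The solid line marks equal levels and the dashed lines a 2-fold difference; under quantile normalization 50 probes lie at least 2-fold higher on day 10 (red) and 77 at least 2-fold lower (blue), a balance that shifts to 6 and 187 with the spike-in probes set equal.

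Most of the 8 highest day 10 values relative to day 0 belonged to miRNAs of pluripotent and proliferating cells. The miR-302-367 cluster, known from pluripotent cells, had 4 detected probes, of which 3 were at least 2-fold higher on day 10. The other, miR-367-5p, was below 0 (log2 difference -0.63, SD 0.28). miR-302d-3p was 5.58-fold higher (log2 difference 2.48, SD 0.12) and miR-302a-3p was 4.13-fold higher (2.05, SD 0.18), with a day 0 signal of 73.9 just above the detection threshold of 70.0. The cluster's median difference was 1.90, above all 10000 random lists (100th percentile), and it was above 0 under every scaling tried. With no detection filter, where undetected probes also counted, it was 0.27. In the miR-17-92 and paralogous clusters, known for promoting proliferation, 11 of 23 detected probes were at least 2-fold higher and none lower. miR-363-3p was 5.08-fold higher (log2 difference 2.35, SD 0.17), miR-19a-3p 3.98-fold (1.99, SD 0.18), miR-18a-5p 3.45-fold (1.79, SD 0.18), miR-19b-3p 3.36-fold (1.75, SD 0.073) and miR-25-3p 2.89-fold (1.53, SD 0.065). The median was 0.82, at the 100th percentile, and turned negative only with the 5S rRNA probes set equal (-0.13). The miR-302-3p members are close in sequence to each other, as are miR-19a-3p and miR-19b-3p and the miR-17-5p relatives. The signal of single members is therefore uncertain, and the counts and percentiles may not rest on separate signals.

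The miR-290 cluster, which spans miR-290 to miR-295 and is the main miRNA cluster of mouse embryonic stem cells, was bright on both arrays, with a median log2 level of 11.80 on day 0 and 12.02 on day 10. All 13 detected probes were above 0 after quantile normalization, 1 of them at least 2-fold. That probe, miR-293-5p, was 2.48-fold higher (log2 difference 1.31, SD 0.10), while miR-291a-3p differed by 0.82 (SD 0.13), and by -0.13 without normalization and -0.34 with the 5S rRNA probes set equal. The cluster's median of 0.36 was at the 86.9th percentile of random lists. It became -0.46 without normalization, -0.29 with the spike-in probes set equal and -0.67 with the 5S rRNA probes set equal, and relative to all detected probes it stayed between 0.14 and 0.93 over 16 settings.

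miRNAs of fibroblasts and the let-7 family were lower on the day 10 array, with list medians below 0 under all 16 settings. With no detection filter these medians shrank to -0.18 for fibroblasts and -0.12 for let-7. The mesenchyme and fibroblast list had 24 detected probes, 10 of them at least 2-fold lower and none higher. Its median difference was -0.75, below all random lists (percentile 0). The probe for miR-199a-3p, which also matches miR-199b-3p, was 5.19-fold lower (log2 difference -2.38, SD 0.17), and miR-221-3p was 3.65-fold lower (-1.87, SD 0.073). The list was not uniform, as miR-23a-3p, miR-24-3p and miR-27a-3p differed by 0.26, -0.086 and -0.055. In the let-7 and miR-98 family, which accumulates during differentiation in many lineages, 3 of 14 detected probes were at least 2-fold lower and none higher, with a median of -0.59 (percentile 0.11). let-7i-5p was 3.88-fold lower (-1.96, SD 0.12) and let-7d-3p 2.85-fold lower (-1.51, SD 0.099). The 5p arms of this family are close in sequence, so the signal of single members is uncertain. The lowest value of any named miRNA was that of miR-125b-5p, a miRNA abundant in neural and mesenchymal cells, which was 5.89-fold lower (-2.56, SD 0.050).

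**Figure D2:**
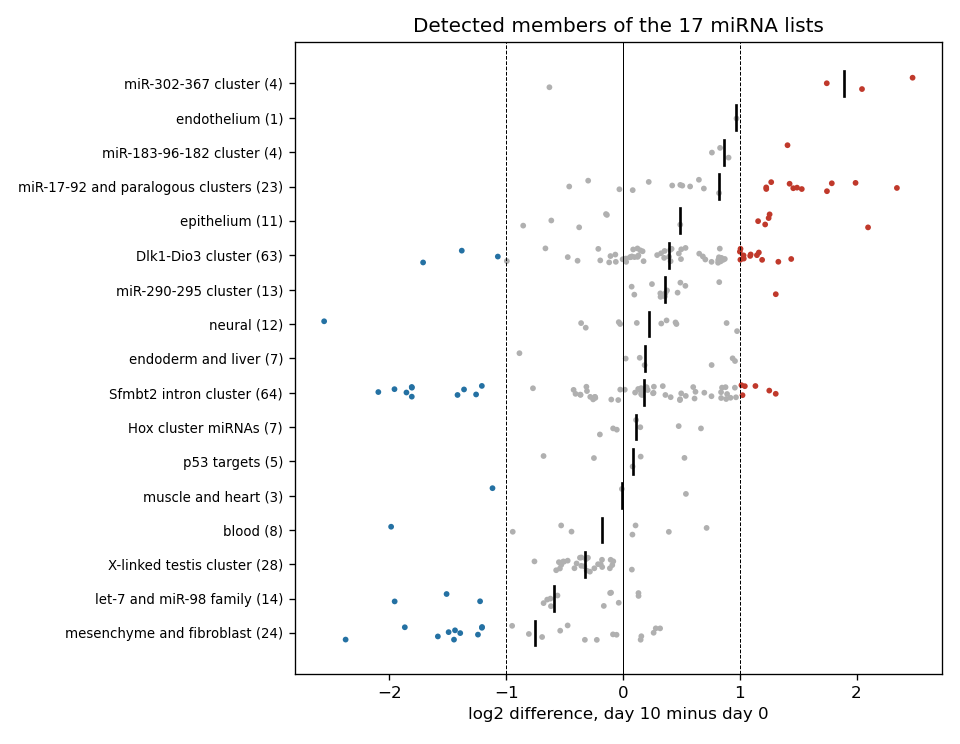
Log2 difference, day 10 minus day 0, of each detected member of the 17 miRNA lists (points, 1 per probe; vertical bars, list medians; number of detected probes in parentheses). Points at least 2-fold higher are red and those at least 2-fold lower blue; medians run from 1.90 in the miR-302-367 cluster to -0.75 in the mesenchyme and fibroblast list, and the medians of 12 of the 16 lists with at least 3 detected probes, such as the miR-290 cluster (-0.29 with the spike-in probes set equal), change sign under at least 1 of 5 other scalings.

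Of 11 detected probes for epithelial miRNAs, 5 were at least 2-fold higher on the day 10 array and none 2-fold lower, while 6 were above 0 and 5 below after quantile normalization. miR-205-5p, found in stratified epithelia, was 4.28-fold higher (log2 difference 2.10, SD 0.081), and miR-200b-3p, of a family that maintains the epithelial state, was 2.39-fold higher (1.26, SD 0.14). The 5p arms of this family that day 0 alone detected had values of -0.14 for miR-200b-5p, -0.38 for miR-200c-5p, -0.61 for miR-200a-5p and -0.85 for miR-141-5p. The list median, the value of the single probe miR-203-3p, was 0.49, at the 99.7th percentile, but it was -0.014 without normalization and -0.23 with the 5S rRNA probes set equal. The miR-183-96-182 cluster, known from sensory epithelia, had 4 detected probes, 1 of them at least 2-fold higher. miR-182-5p was 2.65-fold higher (1.41, SD 0.10), and miR-183-5p differed by 0.90 (SD 0.13), though by -0.0020 with the spike-in probes set equal, -0.17 without normalization and -0.39 with the 5S rRNA probes set equal. The cluster's median of 0.87 was at the 97.8th percentile and became -0.12 without normalization and -0.33 with the 5S rRNA probes set equal.

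The Dlk1-Dio3 cluster, an imprinted region with many miRNAs, had 63 detected probes, 12 at least 2-fold higher and 3 at least 2-fold lower. Among the lower, the target of miR-493-3p (-1.07) holds UGUGUG, a repeat taken up below. miR-154-3p was 2.71-fold higher (log2 difference 1.44, SD 0.054). miR-667-5p was at least 2.88-fold lower, as the day 10 array did not detect it. The median of 0.39 was at the 100th percentile, yet it was -0.25 without normalization, -0.083 with the spike-in probes set equal and -0.47 with the 5S rRNA probes set equal. Relative to all detected probes it stayed between 0.11 and 1.56.

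In the Sfmbt2 intron cluster, a large repeat-derived family, 64 probes were detected, of which 6 were at least 2-fold higher and 10 at least 2-fold lower. Of the named members, miR-669e-5p was 4.27-fold lower (log2 difference -2.10, SD 0.18) and miR-297a-5p was 3.88-fold lower (-1.96, SD 0.26). Members of this family are nearly identical in sequence, so the signal of single members is uncertain. The cluster's median of 0.18 was at the 72.4th percentile and was negative without normalization (-0.73) and with spike-in (-0.56) or 5S rRNA (-0.94) probes set equal. The X-linked testis cluster had 28 detected probes, none at least 2-fold different, of which 27 were below 0. Its median of -0.32 was at the 1.54th percentile and was below 0 under all 16 settings; miR-741-3p had a difference of -0.76 (SD 0.19) and miR-871-5p of -0.57 (SD 0.040).

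The arrays detected 12 of 30 neural, 3 of 15 muscle and heart and 8 of 17 blood probes. None of 12 neural probes was at least 2-fold higher and 1, miR-125b-5p, was lower; the median was 0.22 (88.9th percentile), but -0.43 without normalization, -0.26 with the spike-in and -0.64 with the 5S rRNA probes set equal. miR-129-5p differed by -0.32 (SD 0.10), and by 0.023 with 75th percentile scaling. Of 3 detected muscle and heart probes, miR-206-3p of skeletal muscle was 2.17-fold lower (-1.12, SD 0.14) and neither of the others reached 2-fold. The target of miR-206-3p holds UGUGUG, a repeat taken up below, so an effect of sequence on its value cannot be told apart. The median was -0.0097 (39.3rd percentile), but 0.38 with 75th percentile scaling and -0.98 with the 5S rRNA probes set equal. Of 8 blood probes, miR-146a-5p was 3.96-fold lower (-1.99, SD 0.022) and 7 were below 2-fold; the median was -0.18 (27.7th percentile), and 0.47 with 75th percentile scaling.

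None of the 7 endoderm and liver, 7 Hox cluster or 5 p53 target probes detected was at least 2-fold different. Their medians were 0.19, 0.11 and 0.082 (66.1st, 88.1st and 54.2nd percentile), and all 3 were below 0 without normalization and with the spike-in (-0.29, -0.31 and -0.49) or 5S rRNA probes set equal. The p53 median was also below 0 with cyclic loess (-0.030). miR-101b-3p differed by 0.94 (SD 0.19) and miR-194-5p by 0.76 (SD 0.041), both below 0 without normalization and with the 5S rRNA probes set equal. miR-196a-5p differed by 0.67 (SD 0.040) and miR-196b-3p by 0.11 (SD 0.039), and miR-34c-3p by 0.53 (SD 0.078) and miR-34b-3p by -0.68 (SD 0.21). Of these, miR-196b-3p and miR-34c-3p were negative without normalization and with the spike-in or 5S rRNA probes set equal, and miR-196a-5p with the 5S rRNA probes set equal. The only detected endothelial probe, miR-126-3p, differed by 0.97 (SD 0.078), and by -0.17 with the 5S rRNA probes set equal.

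Outside the lists, the lowest values belonged to miR-6347 (5.31-fold lower, log2 difference -2.41, SD 0.26), miR-706 (5.01-fold, -2.33, SD 0.084), miR-1306-3p (4.85-fold, -2.28, SD 0.053) and miR-3473d (4.51-fold, -2.17, SD 0.19). The 3 brightest miRNAs were the same on both arrays. They were miR-341-5p, miR-690 and miR-709, with differences of 0.17 (SD 0.29), 0.23 (SD 0.079) and -0.39 (SD 0.32). Quantile normalization gives spots of equal rank the same value, so at the top of the arrays these differences reflect changes in rank. The value of miR-341-5p ran from 0 with medians over spots to 1.88 with 75th percentile scaling, and was 0.74 without normalization. The sign of miR-690 turned with the 5S rRNA probes set equal (-0.16) and that of miR-709 with 75th percentile scaling (0.70).

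**Figure D3:**
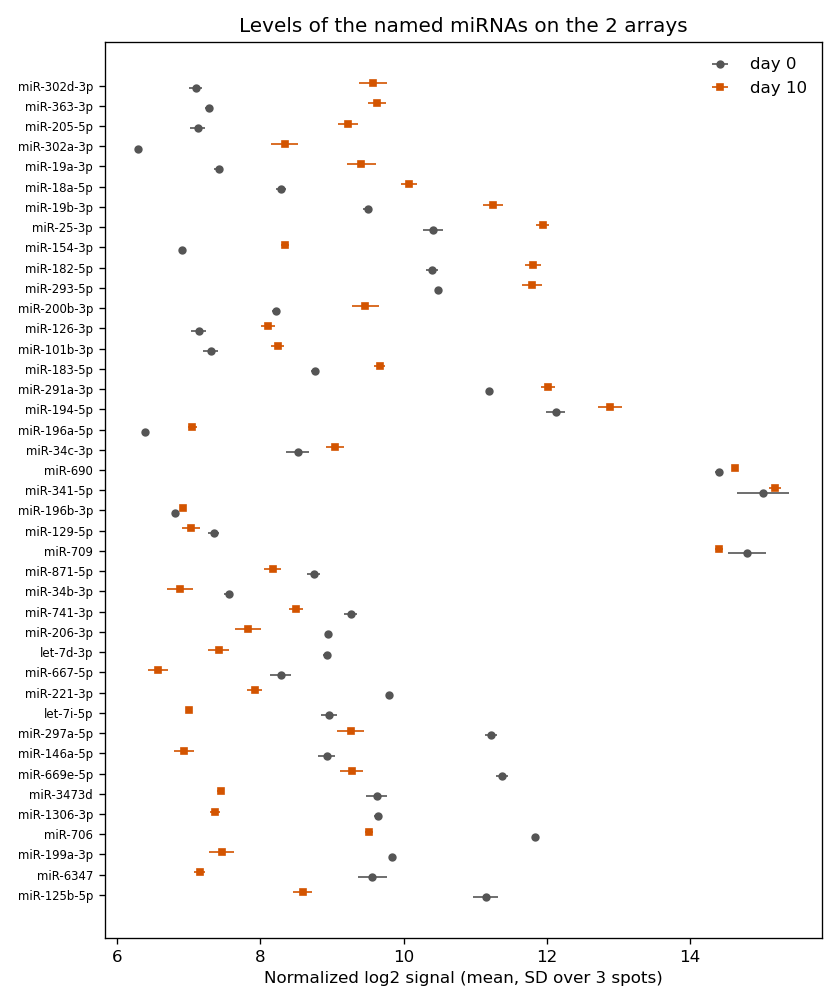
Normalized log2 signal of the named miRNAs on the day 0 array (grey circles) and the day 10 array (orange squares), as mean with SD over 3 spots, ordered by difference. The spot SD is technical; miR-302d-3p at the top differs by 2.48 and miR-125b-5p at the bottom by -2.56, and miRNAs in the middle such as miR-34c-3p (-0.40 with the spike-in probes set equal) change sign with the scaling.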

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

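The blank-spot, 5S rRNA and doubled-threshold settings, and the medians relative to all detected probes, were chosen after the data were seen. Scaling moved the median of the detected probes from 0.024 to -0.63 without normalization, -0.46 with spike-in probes set equal, -0.84 with 5S rRNA probes set equal and 0.52 with 75th percentile scaling, and list medians moved with it. Relative to all detected probes, the miR-302-367, miR-17-92, miR-290, Dlk1-Dio3, miR-183-96-182, epithelial and neural medians stayed above 0, and the let-7, fibroblast, X-linked and blood medians below 0, in all 16 settings. These settings are not all separate checks. No normalization and the spike-in, 5S rRNA and 75th percentile scalings differ by 1 constant, so their relative medians are equal by construction. Among named miRNAs with a 2-fold difference, only miR-200b-3p changed sign (-0.038 with 5S rRNA probes set equal). Local background was not subtracted, since the files have no background column. No paired analysis was possible because each day has 1 array. Signal over background limits the dim probes: 263 of the 739 were not detected on day 10. The spike-in, 5S rRNA and 75th percentile scalings add 1 constant to every unnormalized difference. Causes of the shifts between settings were not tested otherwise, and some possible causes of the patterns are weighed below.

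Without normalization, 6 miRNAs were 2-fold higher and 232 lower, and medians were -0.46 for miR-290, 0.084 for miR-17-92, -1.43 for let-7, -0.73 for Sfmbt2, -0.25 for Dlk1-Dio3, -0.43 for neural, -1.51 for fibroblast, -0.014 for epithelium, -0.12 for miR-183-96-182, -0.46 for endoderm, -0.48 for Hox, -0.66 for p53 and -1.21 for X-linked miRNAs. With spike-in probes set equal, the counts were 6 and 187, and the medians -0.29 for miR-290, 0.25 for miR-17-92, -1.26 for let-7, -0.56 for Sfmbt2, -0.083 for Dlk1-Dio3, -0.26 for neural, -1.34 for fibroblast, 0.049 for miR-183-96-182, -0.29 for endoderm, -0.31 for Hox, -0.49 for p53 and -1.04 for X-linked miRNAs. With 5S rRNA probes set equal, the counts were 3 and 304, and the medians -0.67 for miR-290, -0.13 for miR-17-92, -1.65 for let-7, -0.94 for Sfmbt2, -0.47 for Dlk1-Dio3, -0.64 for neural, -1.72 for fibroblast, -0.23 for epithelium, -0.33 for miR-183-96-182, -0.68 for endoderm, -0.69 for Hox, -0.87 for p53 and -1.43 for X-linked miRNAs. With 75th percentile scaling, 106 miRNAs were higher, and medians were 0.69 for miR-290, 0.42 for Sfmbt2, 0.90 for Dlk1-Dio3, 0.38 for muscle, 0.72 for neural, 0.47 for blood, 0.67 for Hox and -0.067 for X-linked miRNAs.

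Cyclic loess gave 0.20 for miR-290, 0.72 for miR-183-96-182 and -0.030 for p53 miRNAs, and the authors' values gave 0.22 for miR-290, -0.75 for let-7 and -0.49 for X-linked miRNAs. An offset of 16 gave 81 higher miRNAs and 2.51 for miR-302-367. Subtracting the blank spots, with no offset, gave 154 higher and 300 lower, a Pearson r of 0.859, and medians of 4.58 for miR-302-367, 1.49 for miR-17-92, -1.02 for let-7, 1.005 for Dlk1-Dio3, 0.99 for neural, -2.19 for blood, -1.74 for fibroblast, -0.022 for Hox, -1.40 for p53 and -0.82 for X-linked miRNAs. Medians over spots gave 0.023 for muscle and -0.0025 for p53, the first spots 0.52 for miR-290, 0.023 for muscle and -0.035 for p53, and the other spots 0.30 for miR-290. Probes detected on both arrays gave r 0.890, rho 0.824, 0.67 for Dlk1-Dio3 and 1.25 for epithelium. With no detection filter, r was 0.940 and rho 0.922. Medians were then 0.27 for miR-302-367, -0.12 for let-7, 0.019 for muscle, -0.18 for fibroblast, 0.023 for endoderm, -0.027 for Hox and -0.0034 for p53. A doubled detection threshold gave r 0.878, rho 0.797 and 0.73 for Dlk1-Dio3. At 4-fold, 4 miRNAs were higher and 7 lower.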

Other observations

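The miRNAs in the first paragraph and the tests of RNA from other cells, exchanged labels, UG repeats and whole-array signal, with the rules for reading them, were chosen after the results were seen. Outside the fixed lists, 11 miRNAs were at least 2-fold higher on the day 10 array and 48 lower. Among the higher ones were both arms of miR-335 (log2 differences 1.37 for the 5p and 1.30 for the 3p arm), miR-322-5p (1.33), miR-7a-5p (1.26), miR-15a-5p (1.14) and miR-130a-3p (1.04). In scanner signal with neither background correction nor normalization these differences were smaller, with 0.32 for miR-335-5p and -0.13 for miR-130a-3p. The 2 arms of miR-15a went opposite ways, with -1.64 for miR-15a-3p. The same arm of related hairpins was also lower, with -1.86 for miR-16-1-3p and -1.88 for miR-195a-3p. The targets of these 3p arms share the stretch CUGUGCUGC, so their values may not be separate signals. An effect of sequence on them was not tested.

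The day 10 array had miR-302-3p and miR-17-92 family members higher, and fibroblast and let-7 miRNAs lower, which is opposite to the usual course of differentiation. After a linear trend on base composition and level was removed, the medians of the called members were 1.51 (from 1.64) and -1.55 (from -1.45). These members had been picked for their size. The trend explained 9.6% of the variance over 712 other detected probes, so it could hardly remove them. It accounted for little of these members' values, but the whole lists and other sequence effects were not tested. Across detected probes the difference had a Spearman rho of -0.29 with G content. Median G content was 22.2% in all miRNAs at least 2-fold higher and 31.8% in those at least 2-fold lower. How far base composition enters the calls as a whole was not tested. Dilution of the day 0 sample by RNA of other cells stays open for the higher part. The lowest difference of a detected miR-302-3p probe exceeded the highest of the miR-290 cluster by 0.44. However, the 13 detected probes of that cluster themselves spread from 0.074 to 1.31 (SD 0.32). RNA of another cell type in the day 0 sample, such as fibroblast feeder cells, cannot be told apart from a true difference for the lower part, since the fibroblast list median of -0.75 is the observation itself and exchanged labels would give the same direction. Exchanged labels cannot be told apart from a true difference with 1 array per day: the miR-290 cluster median of 0.36 was neither 2-fold higher nor lower, and a biological difference between the days stays open and untested.

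In the Sfmbt2 cluster, 17 of 20 hairpins with both arms detected had the 3p difference above the 5p difference. All 10 members at least 2-fold lower held UGUG. Of 28 detected members with UGUGUG, 16 were below 0 and 10 were at least 2-fold lower. The base composition trend, fitted outside the cluster, took the median gap between arms from 0.61 to 0.12. Detected probes outside the cluster whose target holds UGUGUG had a median of -0.55, against -0.24 inside it, but of the 15 outside it only 9 were below 0, with 7 at least 2-fold lower and 1 at least 2-fold higher. A technical effect of base composition may account for much of the arm difference, and the evidence for UG repeats as such is mixed; the values do not show a switch in arm use.

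The median raw log2 difference of the detected miRNA probes was -0.78, a weaker signal on the day 10 array. Weaker hybridisation or scanning of the whole array as the whole cause would lower the control probes as much. Weaker labelling would do so only for control RNA that was labelled along with the sample. The 19 spike-in probes had a median of -0.24 (SD 0.17), with the lowest at -0.50. These values argue against weaker hybridisation or scanning as the cause of the whole shift. Weaker labelling stays open, as the spike-ins may not report it. The 5S rRNA probes differed by 0.21 in the other direction. They are a limited guide, since the single probes spread from -0.20 to 0.31. The brightest of them, 5S-b1, read 50786 on day 10, against a highest spot signal of 52557, while the others read between 16019 and 43440. Weaker hybridisation or scanning for a part as large as the spike-in shift stays open, as does a lower share of miRNA in the day 10 RNA, which was not tested. At which step the spike-ins were added is not given in the sources used here.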
